A study of Mus musculus with 6 samples.

How the data were processed

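The data are gene-level values from RNA sequencing of 6 mouse samples, 3 of control primary hepatocytes and 3 of hepatocytes overexpressing human YAP-S127A. Groups and replicate numbers came from the sample titles. The authors deposited 1 table of 18037 genes with a count, an FPKM value per library, the mean FPKM of each group, a log2 fold change of those means, and a p-value and a q-value per gene, per the file headers. HISAT2 2.0.4, StringTie 1.3.3b and edgeR, and the genome builds GRCm38.p4 and mm10, are listed in the submitters' processing notes, without their roles or order. The program that made the deposited counts, the strand setting and the handling of reads shared between gene copies are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. In near-identical families (Hba-a1 and Hba-a2, Tgtp1 and Tgtp2, Gbp6, Gbp10 and their relatives, and mt-Atp6 with a nuclear copy, Gm10925) the split of reads is uncertain.

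The deposited counts are whole numbers for all genes and were read with the unit expected counts, and rounding changed none. They sum to 16353328 to 20946701 per library. The ratio of the deposited count to FPKM follows the library totals to within a relative deviation of 5.95e-06, so the authors' FPKM carries no further scaling factor. The rows of 3 genes, Tgfb1, Sirt1 and Bmp4, were broken over lines in the table and were joined again. Gene positions are those of the table. Of the tested genes, 99.7% have an identifier in GENCODE release M21 of GRCm38, and 99.9% of these overlap the position given there.

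Genes were kept by edgeR's filterByExpr with the group, which left 12670 genes holding 99.9% of all counts. Libraries were scaled by TMM, with factors of 1.05, 0.89 and 1.12 for control and 0.76, 1.08 and 1.17 for YAP-S127A. The main test was edgeR's (version 4.0.16) robust quasi-likelihood F test of group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required a change of at least 2-fold. Standard errors are the absolute log2 fold change over the square root of the F statistic. CPM are the values of the edgeR function cpm, counts scaled to the TMM-adjusted library size. The common dispersion corresponds to a biological coefficient of variation of 0.381. Computations used R 4.3.3, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for the remaining tables and figures.

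Before the data were examined, 28 gene lists, the tests, their alternatives and the rule for naming genes were fixed. The rule named Yap1, and the 10 largest changes in each direction among called genes with a mean of at least 5 CPM, no overlap between the groups and a symbol other than a predicted, mitochondrial or ribosomal protein gene. It also named up to 3 called members per list, or the most abundant member where none was called. A few of the genes it picked are not reported here. Lists were tested by limma's camera on log2 CPM with a preset correlation of 0.01, two-sided, and adjusted over the 28 lists. It called 15 lists, 8 higher and 7 lower. Alternatives were camera with an estimated correlation, which called none (lowest adjusted p = 0.661, lowest unadjusted p = 0.0651), not even the cholesterol list whose genes all passed, and fry, a test of whether a list moves on balance in 1 direction, which called 3. Member counts are given over all tested genes and adjusted over the list alone. Another 5 lists (pancreatic acinar enzymes, erythroid genes, plasma cell and immunoglobulin genes, interferon-inducible GTPases and acute phase proteins) were chosen after seeing the data. A fold against a group without counts was computed against a floor of 3 counts over the group, and ratios on 1 to 3 counts carry an exact 95% binomial interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Pathway enrichment used terms of 10 to 300 tested genes and 1-sided Fisher tests adjusted over the 304 terms of each direction.

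Alternatives fixed before the data were examined were the DESeq2 size factors, library size alone, DESeq2, limma-voom, no filter, a filter of 5 CPM, the replicate number as a block, limma-trend on log2(FPKM + 0.1) and leaving out each library. Alternatives meant for a table of FPKM alone were not run, because the authors deposited counts. Chosen after seeing the data were a fit without the 13 mitochondrial genes, a fit without control replicate 2 and YAP-S127A replicate 3, a fit without robust estimation, and a fit with the mean log2 CPM of the Kupffer cell and sinusoidal endothelial lists as a covariate, called the non-parenchymal covariate.

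The edgeR and camera steps were tested on simulated counts of the 12670 genes with the means and library sizes of this comparison. Of genes changed 2-fold, 4-fold and 8-fold, 2.99%, 52.8% and 81.5% were recovered, and 0.05% of unchanged genes were called. A gene not called here can thus have changed 2-fold. Each simulated data set held 200 genes changed by these folds, without the shifts that many genes of a real library share. The shares recovered and falsely called are those of such data and need not hold for the real libraries. Camera called 5 of 5 shifted lists and 0 of 100 unshifted ones. The simulated genes were drawn independently of each other. Members of the real lists correlated, with estimates of 0.612 for cholesterol synthesis and 0.986 for Kupffer cell markers. The 0 of 100 therefore does not measure false calls on the real lists. Single values per library were compared by exact permutation, which with 3 against 3 libraries cannot give a two-sided p below 0.1.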

Results

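RNA sequencing compared primary hepatocytes, the main parenchymal cells of the liver, with and without overexpression of human YAP-S127A. YAP is a transcriptional co-activator that works through the TEAD family of DNA-binding proteins and is restrained by the Hippo kinases. The S127A form lacks a serine that the Hippo kinases LATS1 and LATS2 phosphorylate, and so escapes much of that restraint. The cells came from C57BL/6 mice recorded as 15 weeks old, and messenger RNA was selected from total RNA for the libraries. There were 3 control libraries and 3 YAP-S127A libraries, each a separate sample in the labels. The labels do not say whether the samples of a group came from separate animals or separate cultures, nor how the cells were isolated and kept, so every p-value here measures only the spread between these samples. The libraries held 16353328 to 20946701 gene counts each, and 14245 to 16368 of the 18037 genes in the table had at least 1 count in a given library. The question was which genes change their level when hepatocytes carry the active form of YAP.

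The clearest change was in cholesterol synthesis: all 22 measured genes of this list fell in the YAP-S127A libraries, with a median log2 fold change of -2.90. In fatty acid synthesis 8 of 18 genes fell, in bile acid handling 3 of 19 with 1 higher, and in the list of hepatocyte proteins 5 of 26, while 9 of 14 leukocyte markers, 3 of 18 matrix genes and 5 of 21 Hippo components rose. By camera no gene list passed with an estimated correlation (lowest adjusted p = 0.661). In edgeR's quasi-likelihood test, 1440 of 12670 tested genes differed at an adjusted p below 0.05, 601 higher and 839 lower in YAP-S127A. Of these, 1220 changed at least 2-fold, 543 upwards and 677 downwards. The groups did not overlap in 42.8% of the tested genes, against 10% by chance for 3 libraries against 3. Scaling by library size alone gave 1245 genes with another balance, 792 higher and 453 lower. The count depended on single libraries: it was 5 without control replicate 1, 10 without control replicate 3, 2 without YAP-S127A replicate 1 and 0 without YAP-S127A replicate 2, with 3613, 3458, 3506 and 3233 genes at an unadjusted p below 0.05 in these fits. It was 2936 without control replicate 2 and 3865 without control replicate 2 and YAP-S127A replicate 3 together, the latter an alternative chosen after seeing the data.

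The libraries also differed in ways beyond single pathways. Transcripts encoded by the mitochondrial genome made up 45.7% ± 13 (SD, n = 3) of the counts in YAP-S127A and 17.2% ± 9.96 (SD, n = 3) in control, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. Control replicate 2 stood apart from the other controls with 28.6%, against 10.7% and 12.2%. The YAP-S127A libraries held 58.0%, 46.9% and 32.1%. None of the 13 mitochondrial genes passed the edgeR threshold (median log2 fold change 1.56, lowest adjusted p = 0.0976). The first principal component held 76.6% of the variance and placed control replicate 2 and YAP-S127A replicate 3 as the libraries of their groups nearest to the other group. Spearman correlations between libraries were 0.946 to 0.975 within control, 0.911 to 0.949 within YAP-S127A and 0.779 to 0.938 between the groups, across genes, which are not independent replicates.

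**Figure D1:**
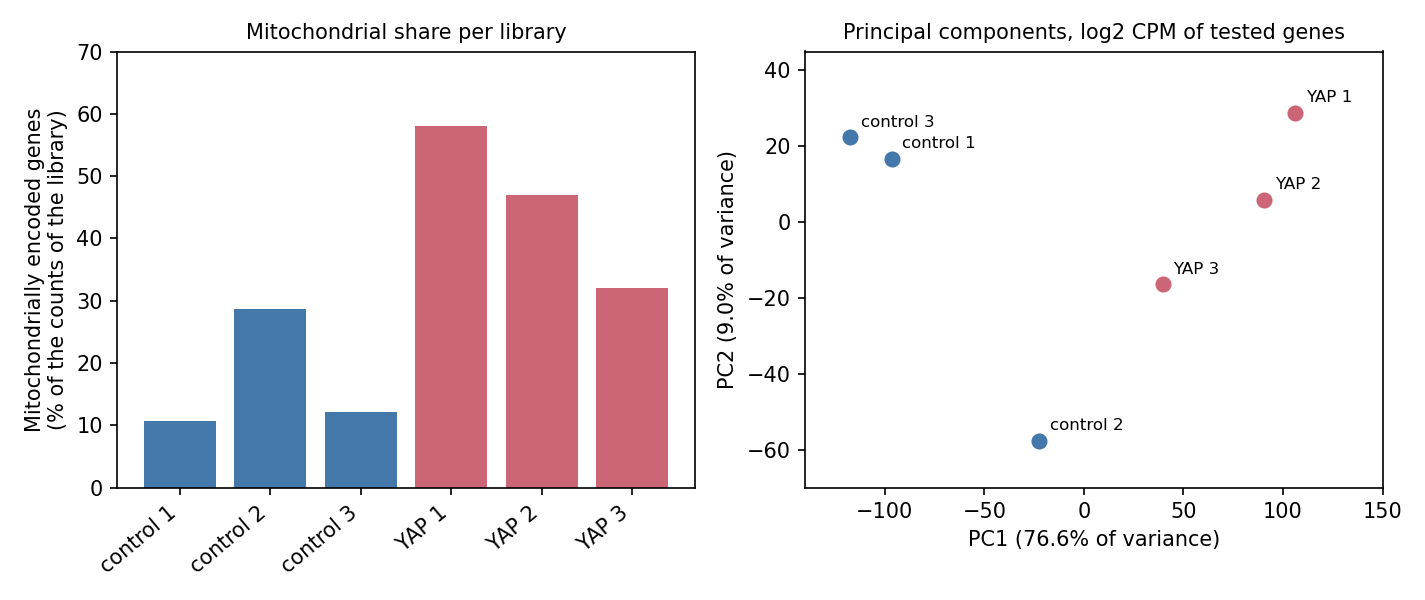
Left, the percentage of each library's counts that fell on mitochondrially encoded genes, 1 bar per library. Right, the first and second principal components of the log2 CPM of the 12670 tested genes, 1 point per library, with control replicate 2 at -22.4 on PC1 and the other controls at -96.6 and -117.3.

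Markers of cells other than hepatocytes moved with the groups and with control replicate 2. The mean log2 CPM of 14 Kupffer cell and macrophage markers was 2.68 ± 2.47 (SD, n = 3) in control and 5.95 ± 0.45 (SD, n = 3) in YAP-S127A. Control replicate 2 reached 5.42, just under the lowest YAP-S127A library at 5.45, while the other controls had 2.01 and 0.62. None of the 14 passed the edgeR threshold, 0 at an unadjusted p below 0.05, against 1 in DESeq2 and 6 in limma-voom. All 14 did without control replicate 2 and none without any other single library. Of 14 markers of liver sinusoidal endothelial cells, Egfl7, a secreted endothelial factor, rose (log2 fold change 3.17 ± 0.75 SE, adjusted p = 0.0466), and adjusted over the list alone all 14 did. All 14 passed in DESeq2, in limma-voom and, in edgeR, without control replicate 2, and none in edgeR without any other single library. That list's mean log2 CPM was 2.50 ± 1.91 (SD, n = 3) in control and 6.54 ± 0.50 (SD, n = 3) in YAP-S127A. None of 15 stellate cell and fibroblast markers passed, adjusted over the list alone none either, with 7 at an unadjusted p below 0.05, 7 in DESeq2 and 5 in limma-voom. Without control replicate 2, 14 of the 15 stellate markers passed, and without any other single library none did.

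By limma's camera these lists were called higher, with adjusted p = 0.000189 for Kupffer cells, 7.53e-07 for sinusoidal endothelium and 6.52e-05 for stellate cells. None of the calls held, with adjusted p = 0.691, 0.661 and 0.661 with an estimated correlation. Clec4f, a lectin of Kupffer cells, counted 211 ± 63.9 CPM (SD, n = 3) in YAP-S127A and 48.8 ± 69.8 CPM (SD, n = 3) in control (adjusted p = 0.249). For Dcn, the matrix proteoglycan decorin of stellate cells and fibroblasts, the means were 65.2 ± 7.20 and 18.3 ± 22.1 CPM (SD, n = 3; adjusted p = 0.198).

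**Figure D2:**
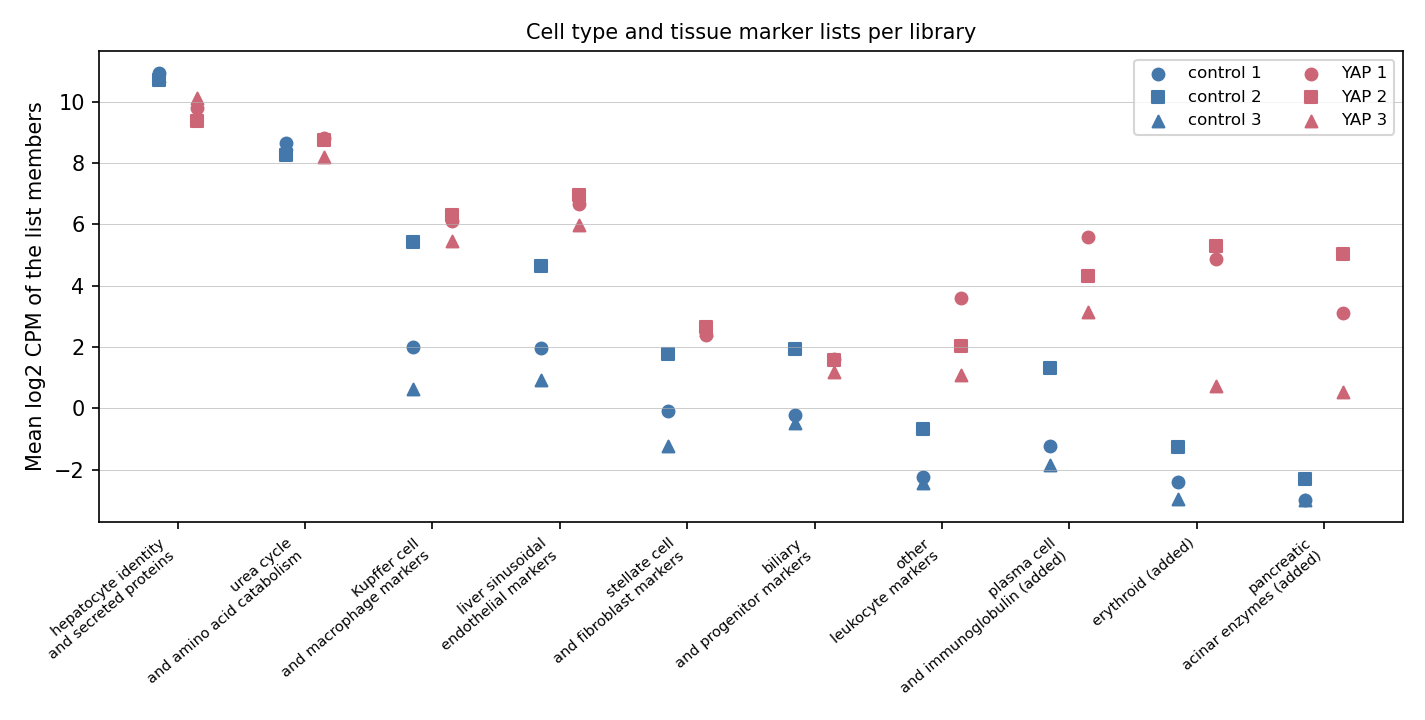
Mean log2 CPM of the members of 10 marker lists in each of the 3 control (blue) and 3 YAP-S127A (red) libraries, 1 symbol per library. Control replicate 2 lies at 5.42 for Kupffer cell markers, beside the YAP-S127A libraries at 6.11, 6.30 and 5.45, and the lists marked "added" were chosen after the values were seen.

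The mouse counterpart of the construct, Yap1 (chromosome 9, 7931999 to 8004596, GRCm38, minus strand), was not called. It counted 51.3 ± 4.34 CPM (SD, n = 3) in control and 59.1 ± 13.5 CPM (SD, n = 3) in YAP-S127A, a log2 fold change of 0.21 ± 0.21 SE (adjusted p = 0.535). Per library the Yap1 counts were 1096, 715 and 1033 in control and 594, 1080 and 1446 in YAP-S127A. Because the construct is human, the mouse gene holds only those of its reads that align to the mouse sequence, so this row does not check the labels.

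Among 18 measured target genes of YAP and TEAD, Ctgf and Lats2 rose and Cyr61 fell. Ctgf, which encodes connective tissue growth factor (chromosome 10, 24595442 to 24598683, GRCm38), counted 8.06 ± 5.97 CPM (SD, n = 3) in YAP-S127A and 0.569 ± 0.505 in control (log2 fold change 3.84 ± 0.92 SE, adjusted p = 0.0478). Its relative Cyr61, a secreted matricellular protein (chromosome 3, 145646976 to 145649981), counted 7.50 ± 3.81 CPM (SD, n = 3) in YAP-S127A and 28.7 ± 10.1 in control (log2 fold change -1.93 ± 0.45 SE, adjusted p = 0.0444). Lats2, the kinase that phosphorylates YAP, was 19.3 ± 1.92 against 9.43 ± 1.299 CPM (SD, n = 3; log2 fold change 1.03 ± 0.18 SE, adjusted p = 0.0337). Adjusted over the list alone, 5 members were higher and 1 lower. The list's median log2 fold change was 0.996 and camera called it higher (adjusted p = 0.0125, and adjusted p = 0.661 with an estimated correlation). With the Kupffer and sinusoidal marker level as a covariate, an alternative chosen after seeing the data, the median was 0.13 and none of the 18 passed in edgeR. Without control replicate 2, 10 of the 18 were higher and 1 lower, without YAP-S127A replicate 3 it was 2 and 2, and none passed without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2.

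Of 21 measured Hippo pathway components 5 rose and none fell, with 9 higher when adjusted over the list alone. Besides Lats2 these were Amotl1, an angiomotin that binds YAP (log2 fold change 3.87 ± 0.68 SE, adjusted p = 0.0342), Map4k4, a kinase upstream of LATS (2.70 ± 0.49 SE, adjusted p = 0.0342), the scaffold gene Sav1 (1.02 ± 0.21 SE, adjusted p = 0.0384) and the kinase gene Stk4 (0.98 ± 0.22 SE, adjusted p = 0.0416). Sav1 and Stk4 fall outside the rule for naming genes and were chosen after their values were seen. Camera called this list higher (adjusted p = 0.00137, and adjusted p = 0.661 with an estimated correlation), and so did fry (adjusted p = 0.0261). With the non-parenchymal covariate none passed in edgeR, while the median went from 0.42 to 0.58 and 18 of 21 fold changes were positive. The calls ended without a smaller median, in a fit whose covariate follows the groups. In the main fit the 5 called genes all lay above the median, so it does not describe them. Control replicate 2 held 3.80 CPM of Amotl1, against 0.866 and 0.652 in the other controls. For Map4k4 it held 4.74 CPM, against 2.23 and 2.12, while Lats2 was not highest there (10.1 CPM, against 10.2 and 7.93). Without control replicate 2, 10 were higher, and none without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2.

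The cholesterol synthesis list covered the route from acetyl-CoA to cholesterol and its regulators, and all 22 genes passed in edgeR, 22 also when adjusted over the list alone. Sqle, which encodes squalene epoxidase (chromosome 15, 59315077 to 59331192, GRCm38), counted 95.2 ± 20.5 CPM (SD, n = 3) in control and 4.13 ± 1.47 CPM (SD, n = 3) in YAP-S127A (log2 fold change -4.52 ± 0.33 SE, adjusted p = 0.0114). Dhcr7, the last reductase of the route (chromosome 7, 143823145 to 143848410), went from 108 ± 15.1 to 8.05 ± 1.55 CPM (SD, n = 3; log2 fold change -3.75 ± 0.24 SE, adjusted p = 0.00810). Fdps, which makes farnesyl diphosphate, had a log2 fold change of -3.81 ± 0.48 SE and the sterol dehydrogenase Nsdhl one of -3.81 ± 0.47 SE, both with adjusted p = 0.0272. The smallest change was that of Srebf2, the transcription factor of the pathway, at -1.26 ± 0.20 SE (adjusted p = 0.0328). Camera called the list lower (adjusted p = 1.37e-15, and adjusted p = 0.661 with an estimated correlation), and fry gave adjusted p = 0.0231. All 22 kept a negative fold change in each alternative fit, but their groups did not overlap, so leaving out a library could hardly turn a sign. The number called was 2 without control replicate 1, 3 without control replicate 3, 1 without YAP-S127A replicate 1 and 0 without YAP-S127A replicate 2, and 4 with the non-parenchymal covariate (median -3.29).

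**Figure D3:**
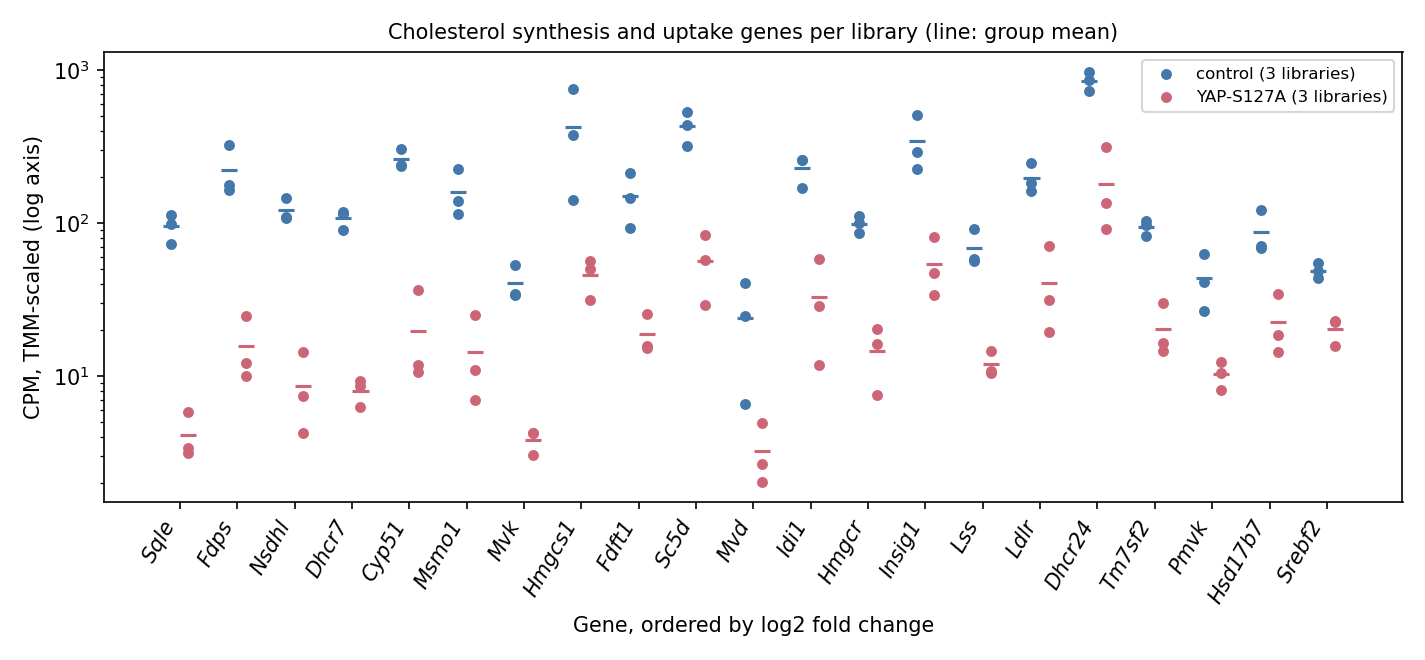
TMM-scaled CPM (log axis) of 21 of the 22 genes of the cholesterol list in the 3 control (blue) and 3 YAP-S127A (red) libraries, 1 point per library, with a line at each group mean. Every YAP-S127A point lies below every control point of the same gene, from Sqle with means of 95.2 and 4.13 CPM to Srebf2 with 48.9 and 20.4 CPM.

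Fatty acid synthesis genes moved the same way in part. Of 18 measured, 8 fell and none rose, and 13 fell when adjusted over the list alone. Scd1, the stearoyl-CoA desaturase, went from 3711 ± 78.7 to 329 ± 102 CPM (SD, n = 3; log2 fold change -3.49 ± 0.38 SE, adjusted p = 0.0261). Srebf1, the transcription factor of lipogenesis, had a log2 fold change of -3.19 ± 0.36 SE (adjusted p = 0.0261) and the desaturase Fads2 one of -2.74 ± 0.41 SE (adjusted p = 0.0319). The median was -1.66, and camera called the list lower (adjusted p = 5.35e-08, and adjusted p = 0.661 with an estimated correlation) while fry gave adjusted p = 0.0231. With the non-parenchymal covariate none passed in edgeR, but the median was -1.60 with 17 of 18 fold changes negative, as in the fit without it. The number called lower was 11 without control replicate 2, 13 without YAP-S127A replicate 3, and 0 without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2.

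Secreted hepatocyte proteins were lower in part, while transcription factors of hepatocyte identity did not pass. Of 26 genes of the hepatocyte list, 5 fell and none rose, with 14 lower when adjusted over the list alone. Hpx, which encodes the haem-binding hemopexin, went from 8023 ± 162 to 2034 ± 492 CPM (SD, n = 3; log2 fold change -1.98 ± 0.35 SE, adjusted p = 0.0337). The protease inhibitor Serpina3k had a log2 fold change of -1.82 ± 0.44 SE (adjusted p = 0.0458) and the fibrinogen chain Fgg one of -1.81 ± 0.43 SE (adjusted p = 0.0454). Camera called the list lower (adjusted p = 7.53e-07, and adjusted p = 0.661 with an estimated correlation). The number called lower was 10 without YAP-S127A replicate 3 and 0 without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2. With the non-parenchymal covariate none passed in edgeR and the median went from -1.13 to -0.79. Among members not called, albumin (Alb) counted 49975 ± 16714 CPM in control and 24993 ± 10730 CPM in YAP-S127A (SD, n = 3; adjusted p = 0.228) and the transcription factor Hnf4a had a log2 fold change of 0.39 ± 0.27 SE (adjusted p = 0.351), both named after their values were seen.

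Most genes of bile acid handling and drug metabolism had negative fold changes, 17 of 19 and 18 of 23, with 1 called higher in each list. Of 19 bile acid genes, 3 fell and 1 rose, with 12 lower and 1 higher when adjusted over the list alone. Slc10a1, the sodium-dependent importer of bile acids into hepatocytes, had a log2 fold change of -2.13 ± 0.38 SE (adjusted p = 0.0337). Abcb11, the canalicular bile salt export pump, had -1.91 ± 0.47 SE (adjusted p = 0.0488), and Nr0b2, the nuclear receptor SHP, named after its values were seen, had -1.51 ± 0.34 SE (adjusted p = 0.0416). Abcc4, an exporter of the basolateral membrane, rose from 0.719 ± 0.939 to 12.7 ± 2.12 CPM (SD, n = 3; log2 fold change 4.20 ± 0.90 SE, adjusted p = 0.0409). Its control values were 0.137, 1.80 and 0.217 CPM, highest in control replicate 2, as were the Kupffer cell and sinusoidal marker levels among controls. The cell type behind its rise was not tested. Camera called the bile acid list lower (adjusted p = 0.000158, and adjusted p = 0.661 with an estimated correlation). Of 23 genes of drug metabolism, 2 fell and 1 rose, with the same numbers when adjusted over the list alone. The monooxygenase genes Cyp2a12 (-2.14 ± 0.40 SE, adjusted p = 0.0345) and Cyp2d22 (-1.32 ± 0.32 SE, adjusted p = 0.0469) fell on the log2 scale, and the sulfotransferase gene Sult1a1 rose (1.46 ± 0.32 SE, adjusted p = 0.0400). Camera called it lower (adjusted p = 0.00209, and adjusted p = 0.691 with an estimated correlation). Leaving out YAP-S127A replicate 3 raised the genes called lower to 14 of 23 here and to 11 of 19 for bile acids, and ended the call of Abcc4, and leaving out control replicate 2 gave 3 and 5. With the non-parenchymal covariate no gene of either list passed in edgeR, with medians of -1.36 for bile acids, against -1.45, and -0.96 for drug metabolism, against -1.22. None was called in either list without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2.

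Lymphocyte genes rose. Of 14 markers of leukocytes other than macrophages, 9 rose and none fell, with 13 higher when adjusted over the list alone. The B cell antigen Ms4a1 had 1 count over all control libraries and 124 over the YAP-S127A libraries, 134-fold (95% counting interval 23.6 to 5337) more in CPM. Cd3d, a chain of the T cell receptor complex, had none in control and 80 in YAP-S127A, at least 28.8-fold higher against a floor of 3 counts over the control group. Intervals and floors cover counting error only. The edgeR adjusted p-values were 0.0345 for Ms4a1 and 0.0406 for Cd3d. The list's median log2 fold change was 5.03, or 4.90 with genes absent from control set to their bound, and camera called it higher (adjusted p = 5.35e-08, and adjusted p = 0.661 with an estimated correlation). Control replicate 2 held 21.8 CPM summed over the list, the other controls 2.55 and 1.85, and the YAP-S127A libraries 381, 128 and 56.7. With the non-parenchymal covariate none of the 14 passed in edgeR and the median was 2.07. All 14 passed without control replicate 2, and none without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2.

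A few matrix and cytoskeletal genes rose, and these lists moved with the markers of non-parenchymal cells. Of 18 extracellular matrix genes 3 rose and none fell in edgeR, with 9 higher and 2 lower when adjusted over the list alone. They were the metalloproteinase inhibitor Timp3 (log2 fold change 4.36 ± 0.80 SE, adjusted p = 0.0349), the collagen chain Col6a1 (3.52 ± 0.81 SE, adjusted p = 0.0428) and the laminin chain Lama5 (3.13 ± 0.76 SE, adjusted p = 0.0483). Of 27 genes of actin and adhesion, 2 rose and none fell, with 9 higher when adjusted over the list alone. These were the tropomyosin gene Tpm4 (2.50 ± 0.44 SE, adjusted p = 0.0337) and the annexin gene Anxa1 (2.89 ± 0.60 SE, adjusted p = 0.0388). Camera called both lists higher, with adjusted p = 0.00131 for the matrix and 0.000659 for actin, and adjusted p = 0.661 with an estimated correlation for each. Summed over the matrix list the level was 1783 ± 322 CPM (SD, n = 3) in control and 968 ± 193 in YAP-S127A. With the non-parenchymal covariate no member of either list passed, and the medians went from 2.08 to 0.25 and from 0.97 to 0.19. Without control replicate 2, 13 matrix and 11 actin genes were higher and 2 matrix genes lower, and none of either list passed without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2.

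The largest rises chosen by the fixed rule were for the most part genes of pancreas, blood and plasma cells. Prss2 and Pnliprp1, a trypsinogen and a lipase-related protein of the exocrine pancreas, had no control count and were at least 258-fold and 227-fold higher against the same floor. Cpa1, a pancreatic carboxypeptidase, was 519-fold higher (95% counting interval 143 to 4295) and the immunoglobulin heavy chain Ighg1 425-fold (117 to 3514), each with 2 control counts. The elastase Cela2a had a log2 fold change of 6.38 ± 1.38 SE and Ighg2c one of 6.81 ± 1.21 SE. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs had 7.78 ± 1.59, 6.65 ± 1.46 and 7.69 ± 1.58 SE. Hba-a1 and Hba-a2 are near-identical copies, so how their reads were split is uncertain. Btnl9, a butyrophilin-like surface protein, varied less within the group, at 28 ± 8.33 CPM (SD, n = 3) against 0.153 ± 0.164 in control (log2 fold change 7.51 ± 0.72 SE). Adjusted p-values of these 10 genes ran from 0.0223 to 0.0491. The Prss2 counts per YAP-S127A library were 119, 559 and 37. Those of Cpa1 were 169, 754 and 38 and those of Ighg1 516, 210 and 60, a spread between libraries that the counting intervals do not cover.

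Among the largest falls chosen by the fixed rule, those outside the cholesterol list were Clec2h, a C-type lectin (log2 fold change -5.84 ± 0.45 SE, adjusted p = 0.0114), and Aqp8, a water channel (-4.61 ± 0.55 SE, adjusted p = 0.0266). Slc22a7, an organic anion transporter, had -4.34 ± 0.79 SE (adjusted p = 0.0348), Elovl3, a fatty acid elongase, -4.22 ± 0.88 SE (adjusted p = 0.0395), and Gbp10, a guanylate-binding protein of a family with near-identical copies, -3.90 ± 0.36 SE (adjusted p = 0.0185). Clec2h counted 20.5 ± 9.83 CPM (SD, n = 3) in control and 0.348 ± 0.048 CPM (SD, n = 3) in YAP-S127A.

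Other metabolic lists held few called genes. In glycolysis 1 of 20 genes rose and 2 fell, with 3 and 3 when adjusted over the list alone: Aldoa, an aldolase (0.75 ± 0.17 SE, adjusted p = 0.0411), rose, and the glucose transporter Slc2a2 (-2.63 ± 0.47 SE, adjusted p = 0.0341) and the liver pyruvate kinase Pklr (-1.58 ± 0.39 SE, adjusted p = 0.0487) fell. Gluconeogenesis had 2 of 11 lower, Gpt, an alanine aminotransferase (-1.39 ± 0.27 SE, adjusted p = 0.0354), and the lactate dehydrogenase Ldhd (-1.21 ± 0.30 SE, adjusted p = 0.0488), and 3 when adjusted over the list alone. Prodh, which opens proline breakdown, was the 1 lower gene of 23 in the urea cycle list (-1.30 ± 0.30 SE, adjusted p = 0.0439), and none passed when adjusted over that list alone. In gluconeogenesis, glycolysis and the NRF2 list the medians (0.02, -0.09 and 0.03) and the means (-0.43, 0.45 and 0.25) of the members differed in sign from each other or from the lower direction of camera, which called none of them (adjusted p = 0.196, 0.994 and 0.994). Glycolysis had 5 higher and 3 lower without control replicate 2, 2 and 1 without YAP-S127A replicate 3, and 5 and 4 in DESeq2. The gluconeogenesis median was -0.79 without YAP-S127A replicate 1. No gene of the glycolysis, gluconeogenesis and urea cycle lists passed in edgeR without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2, nor with the non-parenchymal covariate.

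Nuclear-encoded genes of the respiratory chain had 19 of 20 negative fold changes with a median of -0.32, and none passed in edgeR, with 6 lower at an unadjusted p below 0.05, 5 lower in DESeq2 and 1 in limma-voom. Camera called the list lower (adjusted p = 0.00395, and adjusted p = 0.7 with an estimated correlation). Among pericentral and Wnt genes, none of 16 passed, with 5 lower at an unadjusted p below 0.05, 4 in DESeq2 and 0 in limma-voom, while camera called the list lower (adjusted p = 0.0202, and adjusted p = 0.7 with an estimated correlation). Cyp2e1, the most abundant member, counted 7684 ± 1589 CPM (SD, n = 3) in control and 2991 ± 2617 in YAP-S127A (adjusted p = 0.189). YAP-S127A replicate 3 lay at the control level of the pericentral list, at a mean log2 CPM of 6.06 against 4.08 and 4.82 in the other YAP-S127A libraries. Leaving it out gave 5 genes lower and a median of -1.72, against -0.93, and leaving out control replicate 2 gave 1 higher.

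Immune and growth signalling lists held few genes called in edgeR. Of 17 inflammation genes, Lcn2, the iron-trapping lipocalin (-2.51 ± 0.49 SE, adjusted p = 0.0360), and Orm1, an acute phase glycoprotein (-2.20 ± 0.50 SE, adjusted p = 0.0417), fell and Nfkb2, an NF-kappaB subunit (1.62 ± 0.39 SE, adjusted p = 0.0454), rose, with the same numbers when adjusted over the list alone. Of 22 interferon-stimulated genes 3 fell, Isg15 (-1.56 ± 0.23 SE, adjusted p = 0.0319), Bst2 (-1.42 ± 0.27 SE, adjusted p = 0.0351) and Oasl1 (-1.03 ± 0.22 SE, adjusted p = 0.0388), and 3 when adjusted over the list alone. Of 25 growth factors and receptors, Notch1 (1.88 ± 0.35 SE, adjusted p = 0.0346) and Hgf, the hepatocyte growth factor (3.53 ± 0.80 SE, adjusted p = 0.0441), rose, and both when adjusted over the list alone. Sox4, a transcription factor of progenitor cells, was the 1 gene of 13 biliary and progenitor markers that rose (2.86 ± 0.65 SE, adjusted p = 0.0416), with 1 higher and 1 lower when adjusted over the list alone. Camera called none of these 4 lists, with adjusted p = 0.484 for inflammation, 0.0580 for interferon, 0.917 for growth factors and 0.183 for biliary markers. The inflammation list had a median log2 fold change of -1.17, and DESeq2 called 4 of its genes higher and 6 lower. Its summed level was 9987 ± 8313 CPM (SD, n = 3) in control, with 19585 in control replicate 2, and 1664 ± 775 in YAP-S127A. For interferon-stimulated genes DESeq2 called 2 higher and 3 lower.

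The edgeR counts of these 4 lists depended on control replicate 2. Its mean log2 CPM over the biliary markers, 1.94, was above that of each YAP-S127A library (1.61, 1.57 and 1.20), and Hgf counted 2.54 CPM in it, more than in the other controls. When it was left out, 6 biliary markers were higher and 1 lower (median 2.77, against 0.30), 5 growth factors and receptors higher and 1 lower, 4 inflammation genes higher and 2 lower, and 2 interferon-stimulated genes higher and 3 lower. Leaving out YAP-S127A replicate 3 gave 2 higher and 5 lower among growth factors and none among biliary markers. No gene of these 4 lists passed in edgeR without control replicate 1, control replicate 3, YAP-S127A replicate 1 or YAP-S127A replicate 2, and with the non-parenchymal covariate Lcn2 alone did.

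In 6 further lists no member passed in edgeR, nor when adjusted over the list alone, and camera called none of them. At an unadjusted p below 0.05 there were 2 lower of 20 DNA replication genes, 0 of 12 mitosis genes, and 1 higher and 4 lower of 22 genes of fatty acid oxidation. The stress response list had 1 higher and 1 lower of 14, the NRF2 list 4 higher and 3 lower of 14, and the p53 list 2 higher of 17. DESeq2 called 1, 0, 4, 2, 5 and 2 genes of these lists in the same order, and limma-voom 0, 0, 0, 0, 5 and 0. Camera's adjusted p was 0.274, 0.110, 0.125, 0.288, 0.994 and 0.250. In edgeR without control replicate 2, 1 DNA replication gene and 3 genes each of the NRF2 and p53 lists were higher and 1 NRF2 gene lower, and without YAP-S127A replicate 3, 1 DNA replication gene and 2 NRF2 genes were lower and the stress response list had 1 higher and 1 lower. The most abundant members of the DNA replication, mitosis, stress response, NRF2 and p53 lists were Mcm10 (log2 fold change -1.22 ± 0.42 SE, adjusted p = 0.0960), Mki67 (1.90 ± 0.88 SE, adjusted p = 0.187), Hsp90b1 (-0.46 ± 0.44 SE, adjusted p = 0.499), Mgst1 (-1.92 ± 0.50 SE, adjusted p = 0.0534) and Mcl1 (0.57 ± 0.26 SE, adjusted p = 0.184).

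**Figure D4:**
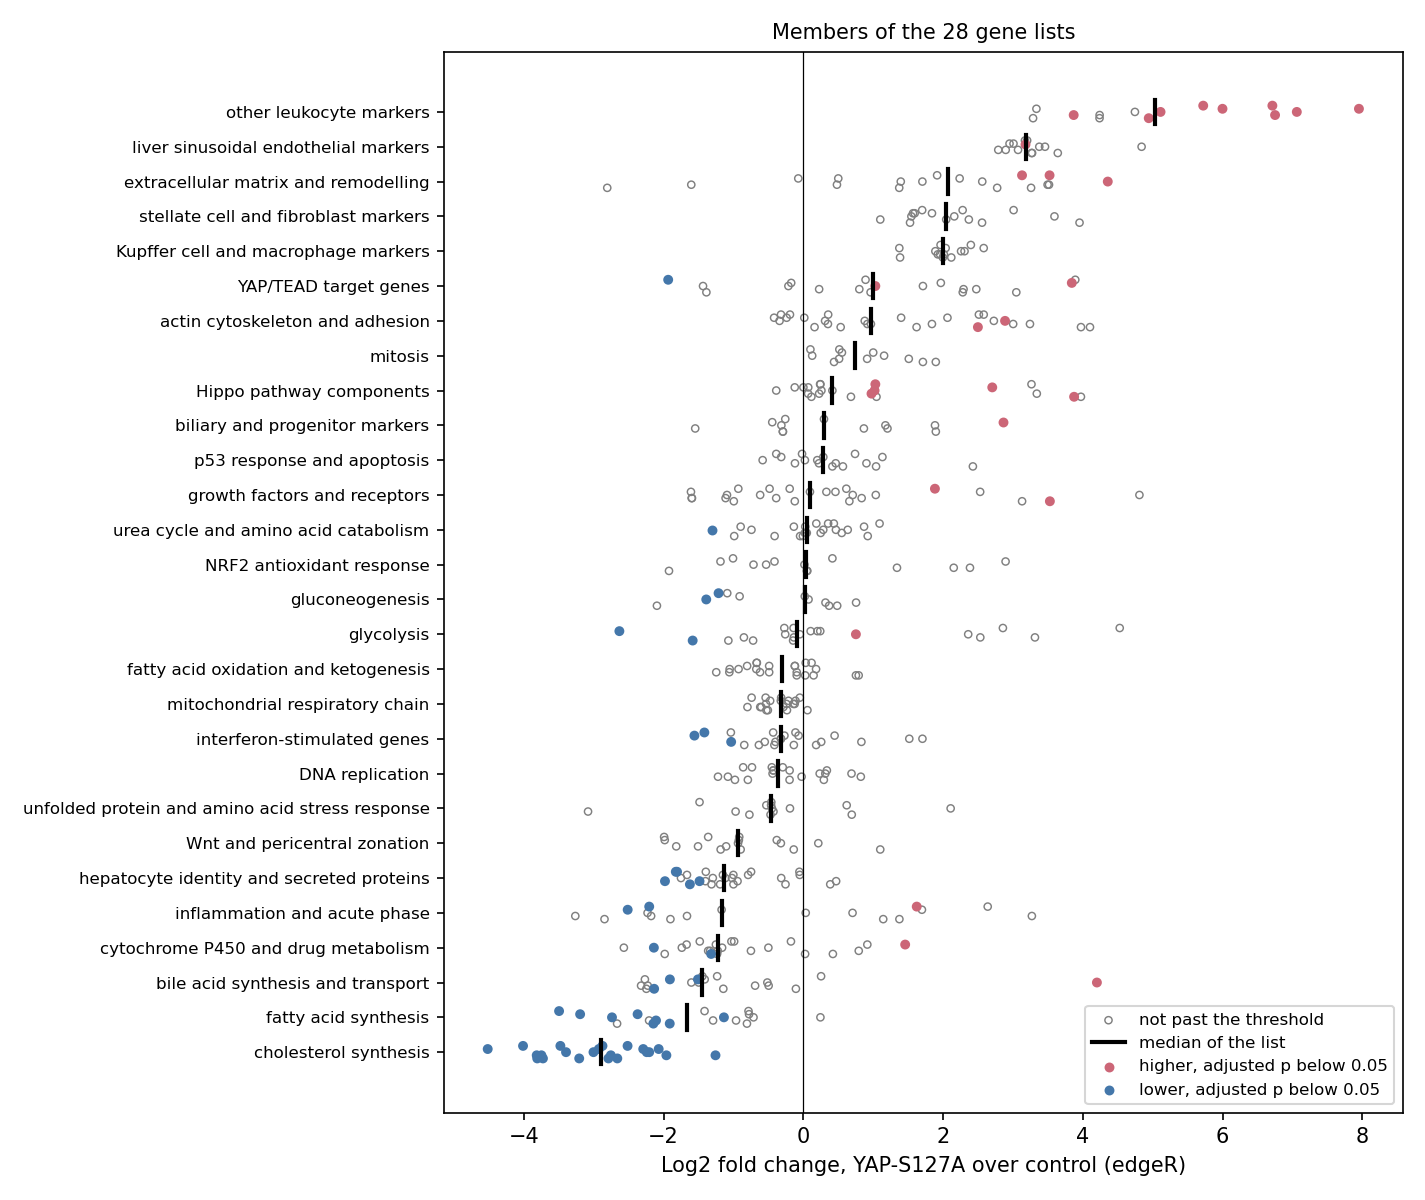
Log2 fold change (YAP-S127A over control, edgeR) of each measured member of the 28 gene lists, ordered by the median of the list (black line), with filled points for genes at an adjusted p below 0.05. The medians run from -2.90 for cholesterol synthesis to 5.03 for leukocyte markers other than macrophages, and the fitted values of genes absent from control, such as Cd3d, are no bounds.

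Enrichment of KEGG pathways, as the deposited table assigns them to genes, was tested by Fisher's exact test against 5143 tested genes with a pathway. Among 384 such genes that fell, 13 of 304 terms passed. Steroid biosynthesis held 14 of its 16 tested genes (adjusted p = 3.85e-12) and terpenoid backbone biosynthesis 10 of 19 (adjusted p = 2.44e-05). Complement and coagulation cascades held 28 of 71 (adjusted p = 3.85e-12), among them C8b (-2.17 on the log2 scale) and C9 (-2.05). Lysosome held 24 of 112 (adjusted p = 0.000125), with the acid lipase Lipa at -1.26 and the membrane protein Lamp1 at -1.05. Protein processing in the endoplasmic reticulum held 24 of 152 (adjusted p = 0.0108), with the translocon subunit Sec61a1 at -1.56 and the disulfide isomerase P4hb at -1.78. These pathway members were chosen after their values were seen. Among 245 genes that rose, 17 terms passed, led by Th1 and Th2 cell differentiation with 18 of 69 genes (adjusted p = 5.09e-07), MAPK signalling with 26 of 209 and hematopoietic cell lineage with 13 of 64 (both adjusted p = 0.000716). Genes are not independent replicates, so these values describe the gene lists. The terms of both directions rest on calls of which few or none were left in some other edgeR fits. With the non-parenchymal covariate 0 genes were called higher and 13 lower. Without control replicate 1 the numbers were 1 higher and 4 lower, and without control replicate 3 they were 2 and 8. Without YAP-S127A replicate 1 they were 0 and 2, and without YAP-S127A replicate 2 they were 0 and 0.

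The authors' deposited table marked 2634 genes as up and 1393 as down, and each marked gene had a p below 0.05 and at least a 2-fold change of mean FPKM. It marked 1227 of the 1440 genes called here in the same direction and none in the opposite one. The marks follow the p-value and a fold limit, while the 1440 rest on an adjusted p without one. The deposited q-value was below 0.05 for 3083 genes. Both sets come from the same libraries, so the shared direction is no separate support. The deposited q-values were 5.47e-22 for Sqle, 0.000214 for Ctgf, 0.000300 for Cyr61 and 0.839 for Yap1.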

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

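The fits without mitochondrial genes, without 2 libraries together, without robust estimation and with the covariate were chosen only after the result was seen. All 1440 genes kept the sign of their change in every fit that tested them, and no named gene reversed. The groups overlapped in none of the 1440, so leaving out a library could hardly turn a sign. The kept signs therefore do not measure how well the calls hold. Yap1 stayed uncalled in every fit, with log2 fold changes of -0.01 to 0.44. The number of genes called, and of those changed at least 2-fold, was 3290 and 2485 in DESeq2, 2173 by limma-voom, 2192 and 2171 by limma-trend on FPKM (62.4% of the calls higher, against 41.7%), and 811 for the 2-fold count with the 5 CPM filter, which tested fewer genes. The cause of these moves was not tested. Without single libraries, fits that rest on fewer samples, both counts ran from 0 to 2936 and from 0 to 2773. Lists called by camera were 0 with an estimated correlation and 3 by fry, and 14 to 18 without single libraries. Same-numbered replicates did not deviate together in all pairs (correlations -0.10, 0.19 and 0.30, and 2 of 3 controls correlated best with another number), so the numbers are not read as pairs. A replicate block gave 620 genes and 605 at 2-fold.

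Of the alternatives chosen after seeing the data, 2 libraries left out together gave 3865 genes and 3717 at 2-fold, sharing 1320 with the 1440. The non-parenchymal covariate gave 13 and 13, all lower and all among the 1440, and of the lists that camera called with or without it, 3 turned downwards: biliary markers (adjusted p = 0.0176), stellate cells (adjusted p = 0.950) and Kupffer cells (adjusted p = 7.94e-05), the last being part of the covariate itself. That covariate follows the groups, which lowers the power of the fit. Leaving out mitochondrial genes gave 1474 genes and no robust estimation 1541. Depth was alike in all libraries, but at 58.0% mitochondrial counts YAP-S127A replicate 1 kept the fewest others.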

Other observations

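The lists and all weighed tests in this part were chosen after the values were seen, except the other splits of the samples, which were planned. Acute phase proteins, which hepatocytes secrete in inflammation, had 7 of 22 genes lower and none higher, and 16 lower when adjusted over the list alone, and 11 of them belong to other lists. Apcs, the serum amyloid P component, had the largest fall in the list, from 377 ± 151 to 32.8 ± 11 CPM (SD, n = 3; log2 fold change -3.52 ± 0.44 SE, edgeR adjusted p = 0.0272). Camera gave adjusted p = 0.229 for this list with an estimated correlation. Interferon-inducible GTPases went both ways, with Tgtp1 (2.90) and Tgtp2 (3.21) higher and Gbp10 (-3.90) and Gbp11 (-3.19) lower out of 15 on the log2 scale. Snhg11, a noncoding host gene of small nucleolar RNAs, had the lowest adjusted p of all genes (0.00572) and a log2 fold change of -3.68 ± 0.20 SE. Snhg11 and Dhcr7 were the genes called without YAP-S127A replicate 1, and both stayed among the 13 called with the non-parenchymal covariate, together with Sqle, Mvk, Lss, Clec2h and Fabp5. Nnt, the mitochondrial transhydrogenase gene that carries a deletion in some C57BL/6 substrains, counted 85.7 ± 8.75 CPM in control and 31.9 ± 2.82 in YAP-S127A (SD, n = 3; log2 fold change -1.42 ± 0.17 SE, adjusted p = 0.0261).

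Within the mitochondrial genome, mt-Atp6 counted 4.69% of mt-Co1 in control replicate 3, against 26.9% to 36.7% in the other libraries, while mt-Co3 lay between 22.5% and 31.1% of mt-Co1 in all 6. With the counts of its nuclear copy Gm10925 added, the sum of both was 10.1% of mt-Co1 in that library and 32.3% to 43.7% in the others.

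The mean levels of the acinar, erythroid and immunoglobulin lists were higher in each YAP-S127A library than in any control, and 9 of 14 leukocyte markers rose. Among 15 acinar genes tested 4 passed and 15 did when adjusted over the list alone, among 8 immunoglobulin genes 5 and 7, and among 3 erythroid genes 3 and 3, with adjusted p = 0.229 for each by camera with an estimated correlation. The 3 erythroid genes are the haemoglobin genes already named among the largest rises. The acinar and immunoglobulin lists also hold genes named there, so these member counts are no separate support. A single source of other-cell RNA, or a lower hepatocyte share alone, runs against the finding that the acinar list moved relative to the Kupffer list by 3.65 log2 units over the YAP-S127A libraries, while the sinusoidal list moved by 0.13. RNA of pancreatic tissue carried over into the preparations may account for the acinar part: Pnlip, Cel and Cpb1, with 1893, 1149 and 1114 counts, had none in control and Cela2a had 10, 18 and 4 there against 351, 2118 and 98, but the lowest correlation of the 15 genes between these libraries, 0.84, lay between the values set for and against. Pnlip, Cel and Cpb1 were not called in edgeR (adjusted p = 0.0601, 0.0583 and 0.0504). YAP-S127A replicate 2 held most of their counts, 1581, 968 and 903. For Kupffer cell markers, none of which passed, a response to YAP-S127A and a difference between preparations cannot be told apart. Control replicate 2 came within 0.0313 log2 units of the lowest YAP-S127A library, and the labels do not describe the preparations, which may differ with the group.

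The fall of cholesterol synthesis genes was weighed against a lower share of hepatocyte RNA and against scaling. Measured from the hepatocyte list in the same library, the cholesterol list was still lower in YAP-S127A by a difference of -1.95 log2 units (group means -5.80 ± 0.32 and -3.86 ± 0.46, SD, n = 3), which argues against the hepatocyte share as the whole cause, as does a difference of -3.08 from the urea cycle list, whose genes are also hepatocyte genes. Scaling moves all lists of a library alike, so the latter difference, with a pooled SD of 0.745, also argues against scaling by the mitochondrial share. The hepatocyte and urea cycle lists themselves changed by -1.06 and 0.0708 in mean log2 CPM, so neither alone measures the hepatocyte share. The cholesterol list, at -3.01, fell further than each. A response to YAP-S127A may underlie the fall, but it stays open. The median log2 fold change of the target genes of YAP and TEAD went from 0.996 to 0.13 with the non-parenchymal covariate, which follows the groups. That value lay between those set for and against, and it does not measure the cholesterol genes. In the same fit the cholesterol list had a median of -3.29, with 22 of 22 fold changes negative and 4 genes called. Sterol supply, culture and isolation were not tested and could differ with the groups.

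The higher share of mitochondrial reads in YAP-S127A was weighed against a rise of the whole respiratory chain programme and against loss of cytoplasmic RNA. The median log2 fold change of its nuclear-encoded members was -0.32 against 1.56 for the mitochondrial genes, which argues against the first. Loss of cytoplasmic RNA before lysis may leave mitochondrial and nuclear RNA behind, and stays open: the nuclear RNAs Malat1 and Neat1 had log2 fold changes of 0.17 ± 0.36 SE and 0.84 ± 0.37 SE, neither past the threshold (adjusted p = 0.779 and 0.161). A response of the mitochondrial genome to YAP-S127A was not tested.

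The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 1440 genes and 1220 at 2-fold, and the highest of the other splits 0 and 0, so 1 split reached each real count. Each other split puts libraries of both groups on each side, so a difference between the groups adds to its spread and lowers its gene count. The 0 therefore does not measure what samples without a group difference would give. For lists called by camera the real split gave 15 and the highest other 18, and 4 of the 10 splits gave as many.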
